A study of Mus musculus with 12 samples.

How the data were processed

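Gene expression was measured by 1-colour Agilent mouse arrays (Cy3) in LSK cells of the bone marrow of C57BL/6 mice with the NS-GFP transgene. Per the labels, 4 fractions were sorted by NS-GFP level, 3 samples each, total RNA was isolated with TRIzol, and a service company processed the arrays. Scanner software, background correction and the treatment of repeated spots are not given in the sources used here.

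The deposited signal tables hold 1 value per probe in units of intensity for 42071 probes, without flags, background values or negative controls. This unit was taken from the column names and from the values, which ran from 4.27 to 450066. The deposited value table of the series holds log2 values, and its columns showed that the authors had quantile normalized them. The sorted columns differed by at most 0.155, and each column kept the ranks of its array's signal, except that of NS-GFP3+ replicate 3 (rank correlation 0.983). The method of that normalization is not given in the sources used here.

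The signal table of NS-GFP3+ replicate 3 equalled that of NS-GFP2+ replicate 3 at all 42071 probes. The value table holds separate values for these samples, and the ranks of the repeated signals matched the value table's NS-GFP2+ replicate 3. The signal table of NS-GFP3+ replicate 3 was therefore left out, which left 11 of 12 arrays, 2 of them in NS-GFP3+, and 7 residual degrees of freedom. Comparisons that use NS-GFP3+ are unbalanced in replicate number. The planned design had 12 arrays.

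Control probes (49) were removed. Of 42022 other probes, 24406 were assigned to 1 gene and 17616 had no gene name. Gene symbols came from the probe table of the platform and were compared through Entrez numbers with a reference table: 17660 of 17847 numbers matched and 0 symbols changed. Each array's log2 signal was reduced by the array's 75th percentile, which ran from 8.70 to 9.52. With no flags or negative controls, the brightest 60% of probes by mean were kept (25213 probes, 17029 of them named), and the brightest probe of each gene was used, giving 12556 genes. Between arrays the correlation of log2 signals was 0.968 to 0.996.

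The fractions were compared with R 4.3.3 and limma 3.58.1 (lmFit and eBayes, prior degrees of freedom 2.59), with all 4 fractions in 1 fit, no covariate, and Benjamini-Hochberg adjusted p below 0.05 over the 12556 genes. Comparisons were NS-GFP4+ with NS-GFP1+, the 3 steps between neighbouring numbers, a linear trend over the number, any difference between fractions, and the last step minus the first. Standard errors (SE) are limma's moderated ones, and SD is the spread between the arrays of a fraction. Gene lists (23, with 485 symbols, of which 388 were tested and 97 were not) were tested by camera with a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation as an alternative. Of these symbols 7 stand in more than 1 list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

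The labels do not say what samples with the same replicate number share, so their deviations from the fraction means were correlated. In the signals the 2 NS-GFP3+ arrays deviate as mirror images, so pairs with them decide nothing, and the other pairs of the same number ran from 0.157 to 0.695. In the value table the pairs of the same number ran from 0.159 to 0.726 in the pairwise comparisons made here. The only one below 0.1 was NS-GFP1+ with NS-GFP3+ of replicate 1 (0.0876), which no pairwise comparison uses. The number was therefore treated as a possible pairing of the samples in the pairwise comparisons. The fit fixed beforehand has no block. Values with the replicate number as a block are given beside the main counts or in the part on processing. They are not given for every count of list members. Replicates 1 and 2 correlated with each other too (0.124 to 0.419 in the value table). The median was 0.253 between replicates 1 and 2, against 0.18 within replicate 1 and 0.34 within replicate 2. The check therefore cannot separate a pairing by number from the shift of the replicate 3 arrays. The counts with the block had been seen before this use of the number was decided.

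Named genes followed a rule fixed before the data were examined. In NS-GFP4+ against NS-GFP1+ these were the 12 largest rises and 12 largest falls past the threshold whose arrays did not overlap between the fractions. In each step they were the 4 largest each way, or the 3 smallest p-values where no gene passed. From each list up to 4 called members with the largest change were named, or the 2 brightest where none was called. Gnl3, Kit, Cd34, Flt3, Slamf1, Cd48, Procr, Vwf, Cdkn1c and Ptprc were always given, and Ly6a was on this fixed list but was not tested because no probe carries its name in the probe table. Names that are only a clone or model number were counted without being named. The genes of the difference between steps and the Tceal and Bex families were named after their values were seen.

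The fit was tested on simulated data, made from each gene's mean and normal noise with the gene's moderated SD, with a change added to 200 genes in NS-GFP4+. Of these genes, 27.5% were recovered at a log2 change of 0.5, 88% at 1 and 98.5% at 2, with 0, 16 and 13 false calls, and at a change of 1, 0 of 23 lists were called. The noise was independent between genes and held no shift of the replicate 3 arrays. The simulation therefore does not test the list calls where genes are correlated.

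Alternatives chosen before the data were examined were quantile normalization, an offset of 50 added before log2 (in place of a background model, for which the signal tables hold no columns), no filter, a filter requiring every array to be among the brightest 60%, the mean of all probes of a gene, all probes separately, the value table, an intensity trend with a robust prior, array weights, the replicate number as a block, adjusted p below 0.01, a log2 fold change of at least 1 (pairwise comparisons), only the arrays of the compared fractions, list members of 1 list only, fry, and leaving out each of the 11 arrays. The offset and the form of the stricter filter are exceptions. They replaced planned settings once the signal tables were seen to hold no flags, background values or negative controls. A block for slide or scan was not run, and separate probes were not used for gene lists. Chosen after seeing the data were the value table with the replicate block, leaving out all replicate 3 arrays, keeping the repeated signal table, and a test of gene families by symbol stem. Random splits were drawn 100 times with seed 1. No genome coordinates were used.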

Results

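The study measured gene expression in the stem and progenitor gate of mouse bone marrow, the lineage-negative cells that carry Sca-1 and Kit (LSK cells). The mice were C57BL/6 and carried a transgene, NS-GFP, in which a part of the promoter of nucleostemin (NS, the gene Gnl3) drives green fluorescent protein. LSK cells were sorted by their level of this fluorescence into 4 fractions, named NS-GFP1+ to NS-GFP4+, with 3 samples each. The labels number the fractions by fluorescence without saying which end of the series is brighter, so the text speaks of fraction numbers only. Total RNA of each sample was read on a 1-colour Agilent array. The 75th percentile of the log2 signal lay between 8.70 and 9.52 across arrays, and the number of arrays limits the precision. The signals of NS-GFP3+ replicate 3 repeated those of NS-GFP2+ replicate 3 at every probe, so this array was left out and NS-GFP3+ had n = 2, against n = 3 in the other fractions. Nothing in the labels says whether samples of 1 fraction came from separate animals, so p-values measure only the spread between these samples.

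The expression of 12556 genes was first compared between arrays by principal components. The first component held 43.3% of the variance, and along it the arrays present for each replicate number followed the fraction numbers. Across replicate numbers NS-GFP2+ replicate 3 (3.39) lay above the NS-GFP3+ arrays (0.530 and 2.72). The second component held 21.2% and set the replicate 3 arrays, present for NS-GFP1+, NS-GFP2+ and NS-GFP4+, apart from replicates 1 and 2. Between replicate 3 and the others, 1904 genes were higher and 1332 lower, while 0 genes passed between replicates 1 and 2 (limma; 952 at an unadjusted p below 0.05). On the first component each replicate 3 array also lay nearer the higher fraction numbers than the others of its fraction. Comparisons of NS-GFP3+ with its neighbours lack a replicate 3 array on 1 side, so this shift enters them. Along the first component it makes the middle step smaller and the last step larger.

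**Figure D1:**
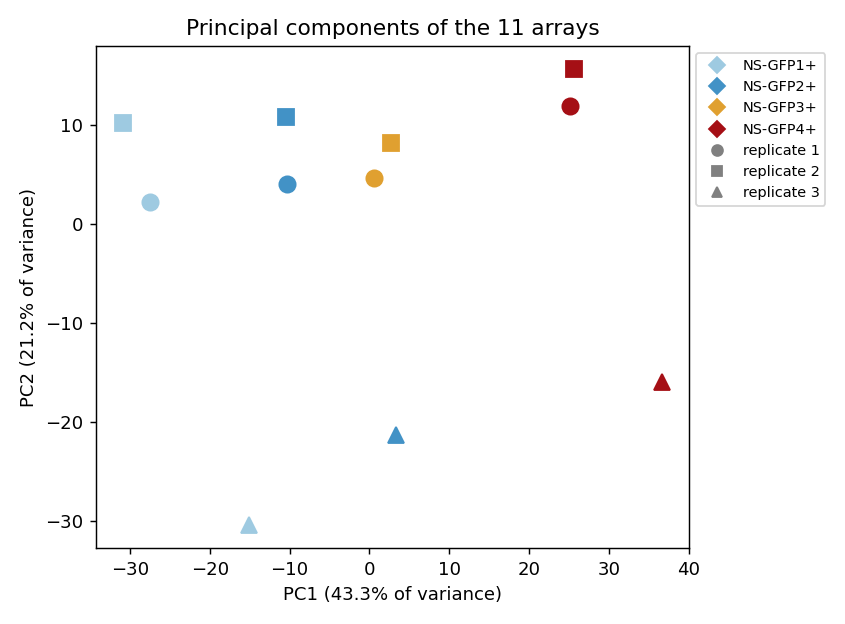
Principal components of the 11 arrays used, with PC1 (43.3% of variance) on the x axis and PC2 (21.2%) on the y axis, in component units; colours mark the fractions and symbols the replicate numbers. Within each replicate number the arrays present follow the fraction numbers along PC1, and the replicate 3 arrays lie between -30.4 and -15.9 on PC2, below all other arrays.

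The first comparison asked how the ends of the series, NS-GFP4+ and NS-GFP1+, differed. The largest falls in NS-GFP4+ included genes known from early B-cell development. Rag1, which encodes a recombinase of antigen receptor genes, had a log2 fold change of -5.20 (SE 0.36), and Igll1, part of the surrogate light chain of the pre-B cell receptor, of -4.75 (SE 0.25). Genes known from long-term stem cells moved the other way: Sult1a1, a sulfotransferase, was higher in NS-GFP4+ by 4.04 (SE 0.15), and Procr, which encodes the endothelial protein C receptor, by 2.14 (SE 0.09). In all, 1148 genes were higher and 889 lower in NS-GFP4+ (n = 3 and 3; limma, Benjamini-Hochberg adjusted p below 0.05), of which 358 and 241 differed by at least 1 on the log2 scale. Without the replicate 3 arrays, an alternative added after the data were seen, 2072 genes passed and 1617 of them were shared with the 2037 above. With the replicate number as a block 3101 genes passed, 1751 higher and 1350 lower.

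**Figure D2:**
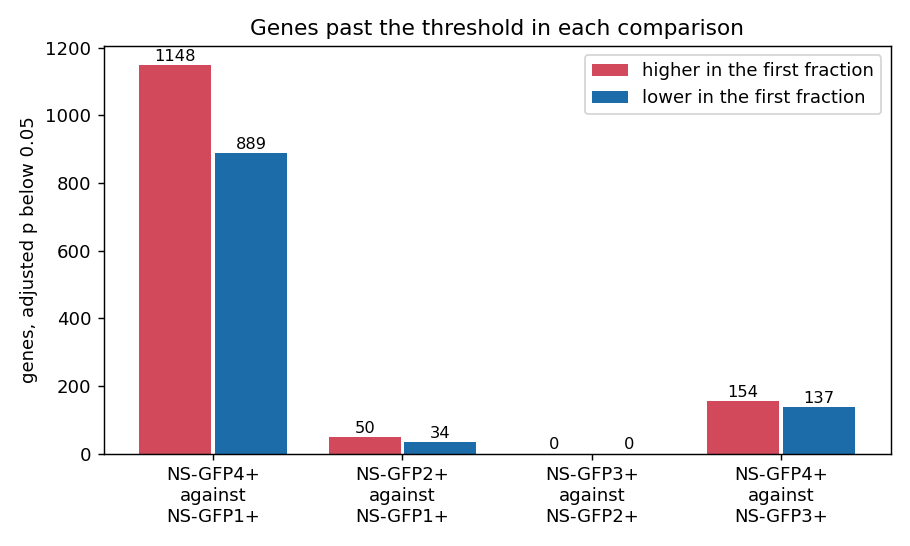
Number of genes past an adjusted p of 0.05 (y axis) in each comparison (x axis); red bars count genes higher and blue bars genes lower in the fraction named first. NS-GFP4+ against NS-GFP1+ gave 1148 and 889 genes, while 0 genes passed between NS-GFP3+ and NS-GFP2+.

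The 12 largest falls in NS-GFP4+ included several genes known from B cells. Beside Rag1 and Igll1 they held Vpreb3 (-4.70, adjusted p = 5.07e-07) and Vpreb1 (-4.04, adjusted p = 3.1e-06), which belong to the surrogate light chain family. They also held Ebf1 (-3.90), a transcription factor needed for B-cell commitment, the B-cell coactivator Pou2af1 (-3.92), the receptor chain Cd79a (-3.77) and the adaptor Blnk (-3.49, adjusted p = 1.57e-07). Ly6d (-3.37), a surface marker of B-biased lymphoid progenitors, and Mzb1 (-3.78), a protein of the endoplasmic reticulum of B cells, fell too. The remaining members were Gfra2, a receptor for glial-derived ligands (-4.50), and Klrd1, a receptor of natural killer cells (-4.18). All 3 NS-GFP4+ arrays lay below all 3 NS-GFP1+ arrays for each of these genes, as the rule for naming them required.

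The 12 largest rises were led by Clip3 (4.57, SE 0.25), a microtubule-binding protein, and Meg3 (4.07, SE 0.37), an imprinted non-coding RNA. Among the others were the transglutaminase Tgm2 (3.43), the ephrin receptor Ephb4 (3.28), the Wnt receptor Ryk (3.22) and the cation channel Trpc6 (3.11). Transcription regulators were also present, with Tcf15 at 3.12 (adjusted p = 2.4e-06), Maff at 3.09 and Tceal3 at 3.56. Npdc1 (3.11), the inhibin subunit gene Inha (3.08) and Sult1a1, given above, completed the set. Of these 24 largest rises and falls, 8 of the rises and 3 of the falls had a fraction mean below the brightness line of the filter. That line lay at -4.04 on the log2 scale relative to the array's 75th percentile. Below it the size of a fold change is uncertain.

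Of the long-term HSC genes, a list fixed, like the other lists and the tests of the comparisons, before the data were examined, 20 of 26 measured members rose in NS-GFP4+ and 0 fell, or 22 and 0 when adjusted over the list alone. Sult1a1, Trpc6 and Procr were joined by Nupr1 (2.60, SE 0.16), a stress-response regulator, and by Slamf1 (1.54, SE 0.17), which encodes CD150. In replicate 3 the list's median was higher by 0.23, and without the replicate 3 arrays 22 members rose and 1 fell. The mean log2 fold change of the list was 1.35 (camera, adjusted p = 1.15e-16; 0.022 with an estimated correlation). Imprinted genes behaved alike, with 8 of 11 members higher and 0 lower, both over all genes and adjusted over the list alone. They included Meg3, Grb10 (2.79, SE 0.22), which encodes an adaptor that dampens growth factor signalling, Cdkn1c (2.30, SE 0.11), which encodes the cell-cycle inhibitor p57, and Ndn (1.59, SE 0.46). The list's mean was 1.35 (adjusted p = 8.85e-08; adjusted p = 0.0288 with an estimated correlation). Of 11 Hoxa and Hoxb cluster genes, 6 rose and 0 fell (8 and 0 when adjusted over the list alone), among them Hoxb2 (2.17), Hoxb3 (1.46), Hoxa10 (1.24) and Hoxa5 (0.64). Their mean was 0.77 (adjusted p = 2.42e-05; adjusted p = 0.0277 with an estimated correlation).

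Lymphoid priming genes fell together: 13 of 16 members were lower and 0 higher in NS-GFP4+, or 14 and 1 when adjusted over the list alone, with a mean of -2.25 (adjusted p = 1.15e-16; adjusted p = 0.0288 with an estimated correlation). The median of the same list in replicate 3 minus replicates 1 and 2 was -0.19, and without the replicate 3 arrays 14 members fell. Among 22 myeloid genes of granulocytes and monocytes, 16 fell and 0 rose, or 17 and 0 when adjusted over the list alone. The largest changes were those of Ly86 (-2.99), Irf8 (-2.32, SE 0.08), a transcription factor of monocytes and dendritic cells, the neutrophil elastase gene Elane (-1.97) and Csf1r (-1.89), which encodes the receptor for macrophage colony-stimulating factor. The myeloid mean was -1.17 (adjusted p = 1.78e-14; adjusted p = 0.022 with an estimated correlation). Of 13 multipotent progenitor genes, 9 fell and 1 rose (10 and 2 when adjusted over the list alone), with Tyrobp (-1.63), Cd52 (-1.14) and Plac8 (-1.02) lower and Mycn (1.01) higher. That list passed with the preset correlation (mean -0.52, adjusted p = 4.22e-05) and by fry (adjusted p = 0.000152). It did not pass with an estimated correlation (adjusted p = 0.151), and its median in replicate 3 minus the others was -0.16.

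Among the fixed genes, many of them surface markers used to divide LSK cells, Flt3 and Cd48 fell. Flt3, a receptor of multipotent progenitors, was lower in NS-GFP4+ by a log2 fold change of -0.87 (SE 0.10, adjusted p = 0.00037), although its call was lost when all probes of a gene were averaged (adjusted p = 0.098), and Cd48 was lower by -0.71 (SE 0.12, adjusted p = 0.00248). Vwf, the von Willebrand factor gene, was higher by 2.59 (SE 0.43, adjusted p = 0.0025). Cd34 differed by only -0.25 (SE 0.07, adjusted p = 0.0381), a call that was lost with quantile normalization (adjusted p = 0.0919). Kit (0.20, SE 0.21, adjusted p = 0.611) and Ptprc, which encodes CD45 (-0.61, SE 0.22, adjusted p = 0.0947), did not pass. Gnl3 itself, the gene whose promoter drives the reporter, did not pass either, at -0.27 (SE 0.10, adjusted p = 0.106). Its means relative to the array's 75th percentile were 1.48 ± 0.06 (SD, n = 3) in NS-GFP1+, 1.37 ± 0.17 (SD, n = 3) in NS-GFP2+, 1.66 ± 0.15 (SD, n = 2) in NS-GFP3+ and 1.21 ± 0.08 (SD, n = 3) in NS-GFP4+, from 1 probe. The 95% interval of the difference ran from -0.50 to -0.05, and only the fit with array weights called it (adjusted p = 0.0218).

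**Figure D3:**
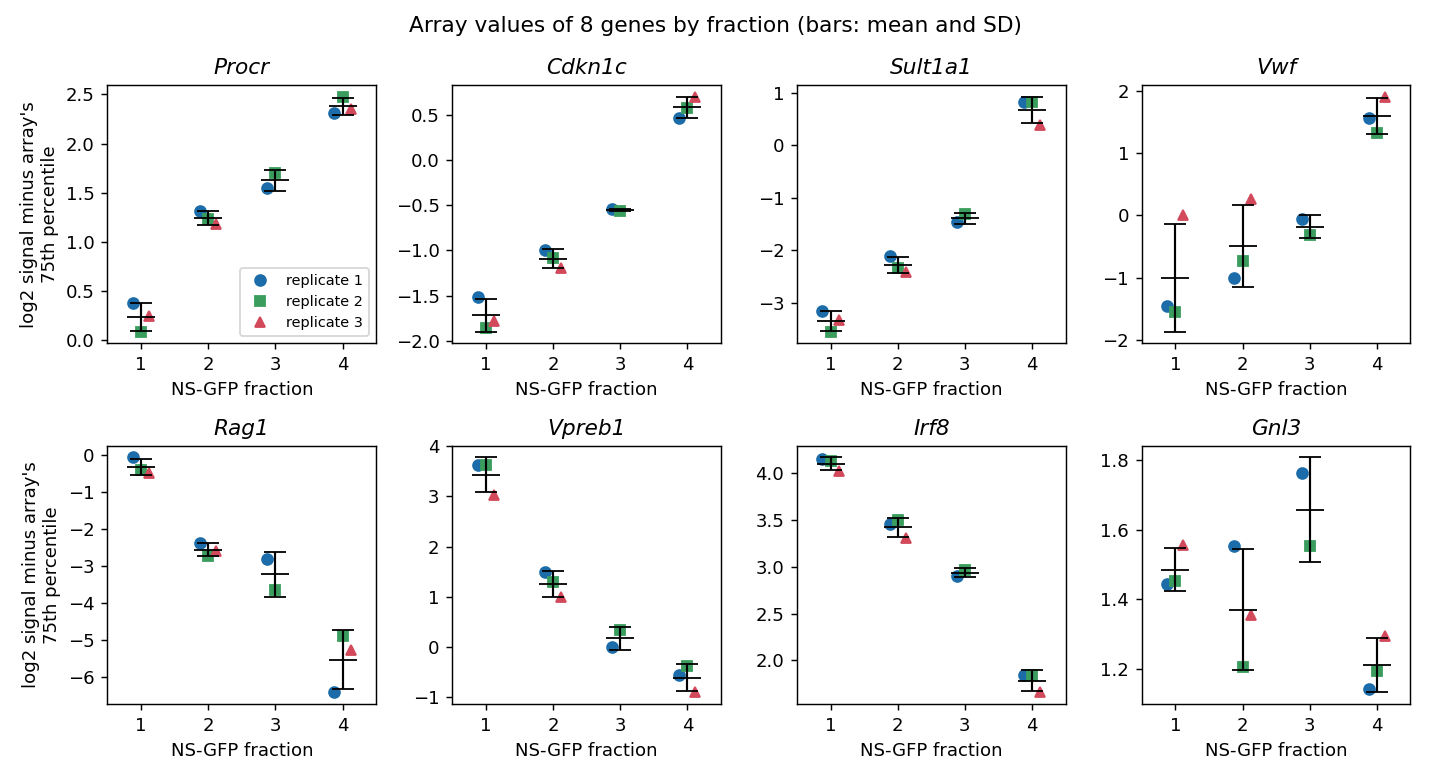
Log2 signal minus the array's 75th percentile (y axis, a separate range in each panel) of 8 genes by NS-GFP fraction (x axis), with 1 symbol per array and black bars for the mean and SD. Procr, Cdkn1c and Sult1a1 climb and Rag1, Vpreb1 and Irf8 descend with the fraction number, and the Gnl3 means stay between 1.21 and 1.66.

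Megakaryocyte and platelet genes were higher in NS-GFP4+ for 7 of 19 members and lower for 0 (10 and 0 when adjusted over the list alone), with Vwf, Mmrn1 (1.92), Rab27b (1.12) and the integrin gene Itgb3 (0.94) the largest. Their mean was 0.79, and the list passed with the preset correlation (adjusted p = 9.01e-06) and by fry (adjusted p = 0.0196). It did not pass with an estimated correlation (adjusted p = 0.367). The same genes were higher in the replicate 3 arrays by a median of 0.635, and without these arrays 17 members rose and 1 fell (16 and 1 with the replicate block). Of 17 erythroid genes, 5 rose and 1 fell (8 and 1 when adjusted over the list alone). The erythropoietin receptor gene Epor (1.27), the globin gene Hbb-b1 (1.22) and Sphk1 (1.57) were higher, and the transferrin receptor gene Tfrc (-0.9999) lower. The erythroid mean of 0.59 passed with the preset correlation (adjusted p = 0.004) and by fry (adjusted p = 0.0387). It did not pass with an estimated correlation (adjusted p = 0.362), and these genes were higher in replicate 3 by a median of 0.501. Under the replicate block 9 rose and 1 fell.

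Genes of the cell cycle differed little. Of 29 DNA replication genes, 2 rose in NS-GFP4+, Prim1 (0.31, SE 0.08) and Rfc5 (0.29, SE 0.08), and 0 fell, while 0 passed when adjusted over the list alone. Of 28 mitosis genes, 5 rose and 0 fell, with the same counts when adjusted over the list alone, among them Birc5 (0.40, SE 0.07), Cdca8 (0.32), Ccnf (0.32) and Bub1 (0.30). Each of these 6 calls was lost under some alternative: Birc5 with the mean of all probes (adjusted p = 0.066), Cdca8 without the replicate 3 arrays (0.0516), and Prim1, Rfc5, Ccnf and Bub1 without a filter (0.0587, 0.0717, 0.0714 and 0.0617). With the replicate block 9 replication and 8 mitosis genes rose. The list means were both 0.16 (adjusted p = 0.00218 and 0.000828; with an estimated correlation, adjusted p = 0.431 and 0.316), and in the replicate 3 arrays their medians were higher by 0.126 and 0.0905. Of 20 cell-cycle inhibitor and quiescence genes, 5 rose and 1 fell (6 and 2 when adjusted over the list alone), with Cdkn1c the largest. The early growth response gene Egr1 followed (2.15, SE 0.21), then Ndn, given above, and Nr4a1 at 0.89. Cdkn1c and Ndn also stand in the imprinted list, and Egr1 and Nr4a1 in the immediate early list. The inhibitor list as a whole did not pass (mean 0.31, median 0.00, adjusted p = 0.246). Immediate early and heat shock genes, which respond to handling of cells as well as to signals, rose for 4 of 21 members and fell for 1, with the same counts when adjusted over the list alone. Egr1, Dusp1 (0.92) and Ppp1r15a (0.84) were among them. That list's mean was 0.42 (adjusted p = 0.00544; adjusted p = 0.388 with an estimated correlation), and it lay 0.266 higher in replicate 3 by its median. With the replicate block 9 of its members rose and 1 fell, and of the inhibitor list 8 rose and 3 fell.

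Nucleolar and ribosome biogenesis genes, the group to which nucleostemin belongs, showed no shift between the ends: 0 of 28 members rose and 1 fell, Wdr43 (-0.27, SE 0.07), with 0 past the threshold when adjusted over the list alone (mean -0.06, adjusted p = 0.172). Of 27 oxidative phosphorylation genes, 0 passed, also when adjusted over the list alone. The brightest of them were Atp5b (-0.16, SE 0.08, adjusted p = 0.236) and Cox4i1 (-0.15, SE 0.08, adjusted p = 0.309), and the list mean was -0.05 (adjusted p = 0.246). Among 23 glycolysis and hypoxia genes, 2 rose, the aldolase gene Aldoc (1.22) and the glucose transporter gene Slc2a3 (0.71), and the oxygen sensor gene Egln3 fell (-0.66). The counts were 3 and 1 when adjusted over the list alone, and the list did not pass (mean 0.05, median -0.00, adjusted p = 0.76). Interferon response genes gave 3 rises, Ifit3 (0.61), Ifih1 (0.57) and Oasl2 (0.51), and 1 fall, Mx1 (-0.62), among 24 members, or 6 and 1 when adjusted over the list alone. Their mean was 0.16 (adjusted p = 0.0534), their median in replicate 3 minus the others was -0.15, and without the replicate 3 arrays the list passed (adjusted p = 0.00819). With the replicate block it passed too (adjusted p = 0.0302), with 9 rises and 2 falls, while the glycolysis list gave 4 and 2.

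Markers of cell types that the gate should exclude were also followed. Mature B cell markers fell for 4 of 8 members, Vpreb3, Vpreb1, Cd79a and Cd79b (-0.81), of which Vpreb1 and Vpreb3 are expressed in B-cell precursors, and rose for 1, with the same counts when adjusted over the list alone (mean -1.75, adjusted p = 5.41e-05; adjusted p = 0.0769 with an estimated correlation). T and NK cell markers fell for 4 of 7 members and rose for 0, with the same counts when adjusted over the list alone. They were Klrd1, Cd5 (-1.29), Cd28 (-1.18) and Nkg7 (-0.34), with a list mean of -1.20 (adjusted p = 0.000494; adjusted p = 0.0288 with an estimated correlation). Of 10 MHC class II genes, 2 fell, H2-Ob (-1.20) and H2-DMa (-0.42), and 0 rose, the same when adjusted over the list alone. The list passed weakly (mean -0.35, adjusted p = 0.0284; adjusted p = 0.438 with an estimated correlation) and its median was 0.689 higher in replicate 3. The call was lost without NS-GFP1+ replicate 3 (adjusted p = 0.156), without NS-GFP4+ replicate 1 (0.129) and without NS-GFP4+ replicate 2 (0.105). Of 9 macrophage markers, 4 rose, Axl (1.27), Spic (0.96), C1qa (0.80) and C1qc (0.61), and 0 fell (6 and 1 when adjusted over the list alone; mean 0.52, adjusted p = 0.0082; adjusted p = 0.289 with an estimated correlation). The macrophage call was lost without a filter (adjusted p = 0.0834) and with the offset added to the signal (adjusted p = 0.0696).

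The other marker lists did not pass between the ends. Of 13 neutrophil markers, Padi4 (0.58) and Ly6g (0.54) rose and Cxcr2 (-0.64) fell, with the same counts of 2 and 1 when adjusted over the list alone (mean 0.19, adjusted p = 0.4). This list stood out in replicate 3, where its median was higher by 1.14. Of 6 mast cell and basophil markers, Il4 rose (3.03, SE 0.17), while Hdc (-1.28), which encodes histidine decarboxylase, and the carboxypeptidase gene Cpa3 (-0.91) fell, with the same counts when adjusted over the list alone (mean 0.68, median 0.06, adjusted p = 0.941). These markers were higher in replicate 3 by a median of 0.412. Of 7 stromal and endothelial markers, Col1a2 (1.22) rose and Pdgfrb (-0.99) and Plvap (-0.87) fell, or 1 and 3 when adjusted over the list alone (mean -0.23, adjusted p = 0.106). Across the 23 lists, 9 were called higher and 6 lower with the preset correlation, and 3 and 3 with an estimated correlation. The calls that held with an estimated correlation were those of the long-term HSC, imprinted and Hox genes on the higher side. On the lower side they were those of the lymphoid priming, myeloid and T and NK cell lists. The correlation was estimated in the fit without the replicate number, so the replicate 3 shift enters it. It was not estimated with the replicate block. Of the list members named above, C1qa, C1qc, H2-DMa, Hoxa5, Ifih1, Ly6g, Mx1, Ndn, Nkg7, Rab27b, Sphk1 and Wdr43 also lost their call under some alternative.

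**Figure D4:**
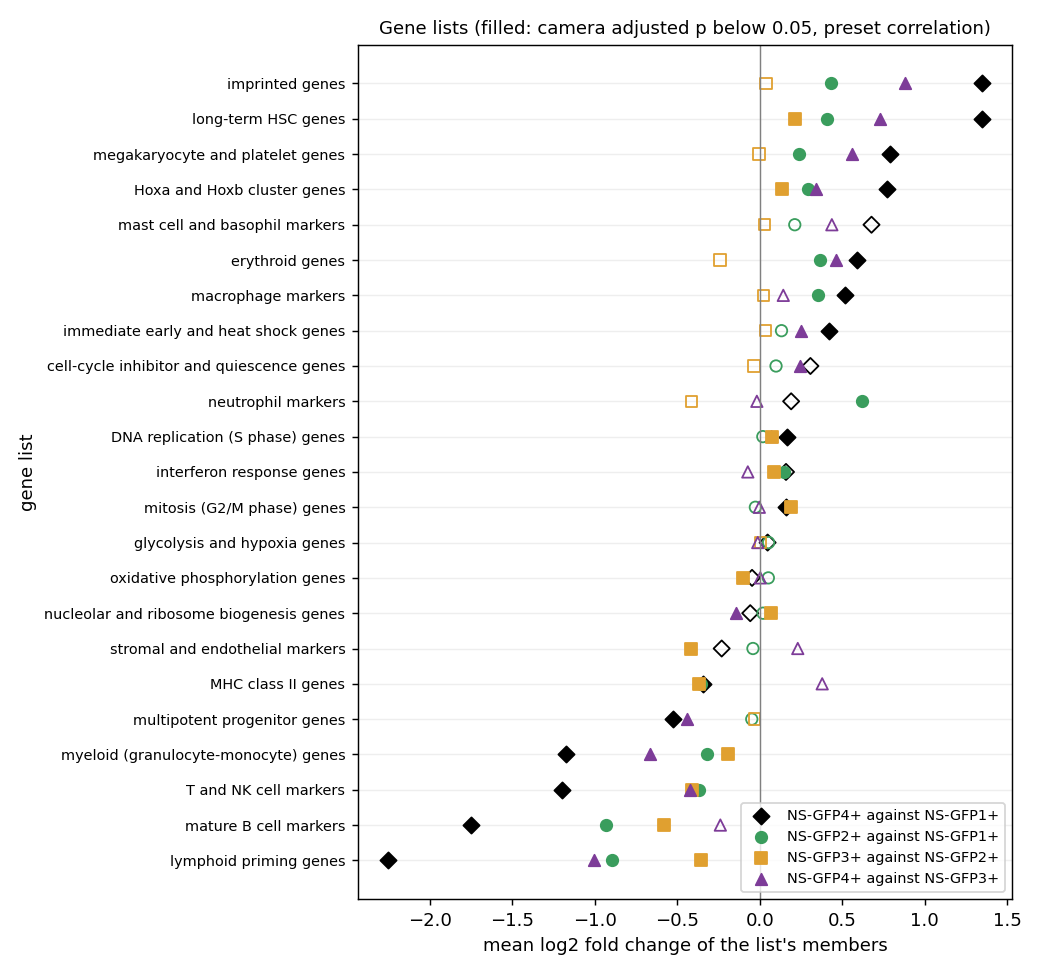
Mean log2 fold change (x axis) of the measured members of each of the 23 fixed gene lists (y axis) in 4 comparisons, shown by symbol and colour; filled symbols passed camera's test at the preset correlation. Lymphoid priming genes lie lowest, at -2.25 in NS-GFP4+ against NS-GFP1+, and long-term HSC and imprinted genes highest, both at 1.35.

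The next comparison concerned the step from NS-GFP1+ to NS-GFP2+. Among the largest falls were those of genes known from B-cell development. Vpreb3 had a log2 fold change of -2.71 (SE 0.17, adjusted p = 0.000216) and Pou2af1 of -2.84 (SE 0.36), with Gfra2 at -2.44 (SE 0.18) and Gpat3, an acyltransferase gene, at -2.55 (SE 0.37). The largest rises were those of Clip3 (2.002, SE 0.25), Inha (1.87), Ephb4 (1.69) and the kinase gene Rps6ka6 (1.26), and these rising genes and Gpat3 had a fraction mean below the brightness line. In the step, 5 of 16 lymphoid priming genes fell (10 when adjusted over the list alone; list mean -0.89, adjusted p = 1.07e-19), and 4 of 26 long-term HSC genes rose (8 when adjusted over the list alone; mean 0.41, adjusted p = 4.81e-10). With an estimated correlation these lists, the myeloid genes (mean -0.32) and the mature B cell markers (mean -0.93) passed, each with an adjusted p = 0.0375. Neutrophil markers were higher as a list (mean 0.62, adjusted p = 0.00208, or 0.46 with an estimated correlation) with 0 members called. Adjusted over the list alone 1 of these markers rose, or 8 with the replicate block. They were also higher in replicate 3, by a median of 1.14.

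In that step 50 genes were higher and 34 lower in NS-GFP2+ (limma, adjusted; 1099 at an unadjusted p below 0.05), 59.5% higher, against 45.9% with the offset added to the signal, 38.8% with each probe tested separately, 16.7% with only the arrays compared and 27.3% without NS-GFP2+ replicate 2. With the replicate block 227 were higher and 112 lower, among them 9 long-term HSC genes higher and 8 lymphoid priming and 6 myeloid genes lower. With the block and adjusted over the list alone, 19 long-term HSC genes rose and 0 fell. Of the 23 lists, 8 were called higher and 5 lower, or 1 and 3 with an estimated correlation. The number depended on single arrays: it was 22 without NS-GFP1+ replicate 1, 31 without NS-GFP1+ replicate 2, 19, 22 and 30 without replicates 1, 2 and 3 of NS-GFP2+, 52 without either NS-GFP3+ array, and 55 and 51 without replicates 1 and 2 of NS-GFP4+. Without all replicate 3 arrays 128 genes passed, 49 of them shared with the 84.

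Between NS-GFP2+ and NS-GFP3+ 0 genes passed (limma, smallest adjusted p = 0.125; 981 at an unadjusted p below 0.05). The smallest p-values were those of Echdc2 (0.72, SE 0.10), Ncf1 (-0.56, SE 0.08), a subunit of the phagocyte oxidase, and Ccdc120 (0.97, SE 0.14). In the value table of 12 arrays, which holds values of its own for NS-GFP3+ replicate 3, 2 genes passed, Echdc2 (0.73) and Ncf1 (-0.54), both with an adjusted p = 0.0301. With the replicate block 1 gene was higher and 11 were lower, and Echdc2 (adjusted p = 0.0322) and Ncf1 (0.0372) passed; Echdc2 was the riser. With the preset correlation, mitosis genes were higher in NS-GFP3+ as a list (mean 0.19, adjusted p = 2.86e-09, or 0.154 with an estimated correlation). Adjusted over the list alone 1 member rose, or 3 with the replicate block. Long-term HSC genes were higher too (mean 0.21, adjusted p = 8.88e-05, or 0.154 with an estimated correlation). Of these, 3 members rose when adjusted over the list alone, or 10 with the replicate block. Mature B cell markers (mean -0.58, adjusted p = 5.08e-06; 0.154 with an estimated correlation; 4 members) and lymphoid priming genes (mean -0.36, adjusted p = 6.85e-05; 0.276 with an estimated correlation; 6 members) were lower. In all 6 lists were called higher and 7 lower. With an estimated correlation 0 of the 23 lists passed in this step. In the value table of 12 arrays, with the preset correlation, megakaryocyte (adjusted p = 0.00428), imprinted (0.00141) and immediate early genes (0.0291) were also called higher. Interferon (0.1785), oxidative phosphorylation (0.384) and MHC class II genes (0.153) lost their calls there. The list means there were 0.33 for long-term HSC and -0.51 for lymphoid priming genes, larger in size than in the signals. The mean of the mature B cell markers was -0.56. Leaving out NS-GFP3+ replicate 1 or 2, which left this fraction with 1 array assumed to vary like the others, gave 8 and 13 genes.

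From NS-GFP3+ to NS-GFP4+ lymphoid priming and myeloid genes fell further. Ly86, a partner of an innate immune receptor, changed by -1.77 (SE 0.20, adjusted p = 0.00403), the coagulation factor gene F13a1 by -1.72 (SE 0.24), Rag1 by -2.30 and Klrd1 by -2.32. Meg3 (2.70, SE 0.41) and Sult1a1 (2.07, SE 0.16, adjusted p = 0.0016) rose, as did Cyp26b1 (2.68), which degrades retinoic acid, and Sbpl (1.997). Of these genes, Meg3, Cyp26b1, Sbpl, Rag1 and Klrd1 had a fraction mean below the brightness line. In the value table of 12 arrays Cyp26b1, Sbpl and Klrd1 did not pass (adjusted p = 0.124, 0.474 and 0.141). Of the lists, 9 of 22 myeloid genes fell (13 and 1 rise when adjusted over the list alone; mean -0.66, adjusted p = 1.5e-13), 9 of 16 lymphoid priming genes fell (13 when adjusted over the list alone; mean -1.003, adjusted p = 1.47e-15), and 6 of 13 multipotent progenitor genes fell (10 when adjusted over the list alone; mean -0.44, adjusted p = 9.55e-08; adjusted p = 0.0925 with an estimated correlation). Long-term HSC genes rose for 8 of 26 members (15 when adjusted over the list alone; mean 0.73, adjusted p = 1.07e-14) and imprinted genes for 5 of 11 (8 when adjusted over the list alone; mean 0.88, adjusted p = 8.3e-09). In the value table of 12 arrays 3 multipotent progenitor genes fell (9, and 1 rise, when adjusted over the list alone). There 6 long-term HSC genes rose (mean 0.63), 4 imprinted genes rose (mean 0.65) and 8 lymphoid priming genes fell (mean -0.85). These means were smaller in size than in the signals, while the myeloid mean was -0.67 with 7 falls. In the signals the adjusted p with an estimated correlation was 0.0266 for the myeloid and long-term HSC lists. It was 0.049 for lymphoid priming and 0.0389 for imprinted genes. Nucleolar genes were slightly lower as a list (mean -0.15, adjusted p = 8.21e-05; adjusted p = 0.142 with an estimated correlation) with 0 of 28 members past the threshold, also when adjusted over the list alone.

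In this step 154 genes were higher and 137 lower in NS-GFP4+ (limma, adjusted; 2109 at an unadjusted p below 0.05), 52.9% higher, against 44.1% with the value table, 43.9% with quantile normalization, 65.7% with the offset, 72.5% with only the arrays compared and 34.1% without NS-GFP3+ replicate 1. Of the 23 lists, 7 were called higher and 5 lower, or 2 and 2 with an estimated correlation. A fit with the replicate block gave 459 genes higher and 364 lower, with 15 long-term HSC genes among the higher. The number was 474 without the replicate 3 arrays, 236 of them shared, and leaving out 1 array changed it most for NS-GFP3+ replicate 1 (41), NS-GFP4+ replicate 3 (94), NS-GFP4+ replicate 1 (115), NS-GFP3+ replicate 2 (121), NS-GFP4+ replicate 2 (135) and NS-GFP1+ replicate 1 (190).

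The steps from NS-GFP1+ to NS-GFP2+ and from NS-GFP3+ to NS-GFP4+ share no array. Genes called higher in both numbered 31, against 0.613 expected for independent lists, and genes called lower in both 13, against 0.371. Both steps were called from 1 fit that shares each gene's estimate of the spread. Calls in both are thus not independent even without a common change, and the expected numbers set no chance level. Across genes, which are not independent replicates, the log2 fold changes of both steps correlated with r = 0.43. Of the 1148 genes higher in NS-GFP4+ than in NS-GFP1+, 59.5% had their largest step between NS-GFP3+ and NS-GFP4+, 31% between NS-GFP1+ and NS-GFP2+ and 9.49% in the middle step. In the value table of 12 arrays these shares were 44.8%, 43% and 12.2%. Of the 889 lower genes, 65.6% had their largest step at the end (67.2% in the value table). A move in the same direction in all 3 steps was seen for 765 of the 1148 (66.6%) and 608 of the 889 genes (68.4%), and in the value table for 1053 of 1227 (85.8%) and 711 of 876 (81.2%).

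A linear trend over the fraction number was called for 1990 genes, 1093 rising and 897 falling (limma, adjusted), and any difference between the 4 fractions for 1257 genes. The latter count was 832 and 820 without replicates 1 and 2 of NS-GFP4+. A direct test of whether the last step differed from the first called 5 genes, named here after their values were seen because there are so few. Lef1, a transcription factor of the Wnt pathway, fell by 2.19 from NS-GFP1+ to NS-GFP2+ (adjusted p = 0.00121) and then differed by 0.12 in the last step, a difference between steps of 2.31 (SE 0.29, adjusted p = 0.0348). Prkcb, a protein kinase C gene of B cells, fell by 1.06 in the first step and differed by 0.40 in the last (difference 1.45, SE 0.16). Clu, which encodes clusterin, Cracr2b and Gm11559 passed only in the last step, where they rose by 1.12, 1.80 and 1.48, with differences between steps of 1.35, 2.06 and 1.66 (adjusted p from 0.0229 to 0.0348). Leaving out any of NS-GFP1+ replicates 1 and 2, NS-GFP2+ replicates 1 and 2 or the 3 arrays of NS-GFP4+ left 0 genes, and without NS-GFP2+ replicate 3 and NS-GFP3+ replicate 2 the test called 8 and 18.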

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

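All tests of explanations in this part were chosen after the results were seen.

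The direct test of the last step minus the first singled out 5 genes, because the effect of a step differed between the ends of the series. The difference was 1.35 for Clu (adjusted p = 0.0229), 2.06 for Cracr2b (0.0229), 1.66 for Gm11559 (0.0348), 2.31 for Lef1 (0.0348) and 1.45 for Prkcb (0.0229). In the value table of 12 arrays Clu (adjusted p = 0.0165) and Lef1 (0.0184) passed, while Cracr2b (0.497), Gm11559 (0.113) and Prkcb (0.113) did not. Without the replicate 3 arrays only Lef1 passed (0.0243). Of 100 splits of the arrays, 4 including the real one called as many genes, and the other 3 called 482, 936 and 54, many times the real 5. The splits moved the labels of all 4 fractions freely, so the differences between fractions and the replicate 3 shift could enter this contrast. They therefore set no chance level for it, and chance is not taken as excluded for these 5 genes. The placement of the replicate 3 arrays alone does not account for the counts, since the split with 936 genes had them in fractions 1, 2 and 4, as the real one did. Leaving out 1 array gave 0 to 18 genes. With the replicate number as a block the test called 27 genes.

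For NS-GFP4+ against NS-GFP1+ (2037 genes, highest other split 0) and NS-GFP2+ against NS-GFP1+ (84 genes, highest other split 0), 1 of 10 splits, the real one, called as many genes, whichever pairs of the same number the others parted, and 10 splits are too few for a share under 0.05. For any difference between the 4 fractions (1257, highest other 367) and for the linear trend (1990, highest other 763), 1 of 100 splits, the real one, called as many. A free placement of the arrays thus seldom reached these counts. The splits ignored the replicate number, so they did not keep a possible pairing of the samples. Chance is therefore not taken as excluded here either.

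The replicate 3 arrays stood apart in every fraction that holds one, with 1904 genes higher and 1332 lower than in replicates 1 and 2. Scaling as the whole cause is argued against, since 3378 genes still differed after quantile normalization. A batch of labelling or hybridization could be a cause: of 81 genes of sensory receptor, hair keratin and defensin families, 21.0% differed in replicate 3, against 24.2% of genes of like brightness. Other marrow cells or their RNA might explain the neutrophil markers, higher by a median of 1.14 (S100a9 rose from 5.01 to 6.08 and Camp by 1.27), but not the 59 genes lower by 1 log2 unit or more, because added cells would lower the long-term HSC list alike, whose median difference was 0.23. Along the first component each replicate 3 array also lay nearer the higher fraction numbers than the others of its fraction. In NS-GFP1+ it lay at -15.1 against -27.4 and -30.9, and in NS-GFP4+ at 36.7 against 25.2 and 25.7. As in NS-GFP4+, megakaryocyte genes were higher (15 of 19) and lymphoid priming genes lower (8 of 16). Hox and MHC class II genes went the other way (medians -0.156 and 0.689). The design names no group that sets replicate 3 apart. No biological explanation was tested, such as a difference in the sorted cells.

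Gnl3 was not higher in NS-GFP4+ although its promoter region drives the reporter. The lower bound of the 95% interval of its difference was -0.502. This argues against a difference of 2-fold or more between the end fractions in the transcript relative to the array's other signals. A difference per cell cannot be decided, because each array was scaled to its own signals. The interval reflects only the spread between arrays. The value rests on 1 probe, and the labels do not state which fraction is brightest. Reporter stability, regulation after transcription and regions missing from the transgene may each separate fluorescence from the transcript and were not tested.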

How the results depend on the processing

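No named gene, and no list past the threshold in NS-GFP4+ against NS-GFP1+, changed sign under any alternative that tested it. The means of lists that did not pass did so in places, such as the mast cell list with the stricter filter (-0.51) and the neutrophil list with array weights (-0.18). The balance of higher and lower calls also turned: in the first step from 50 and 34 to 28 and 33 with the offset, 20 and 25 without a filter and 3 and 15 with only the arrays compared, and in the last step from 154 and 137 to 111 and 142 with quantile normalization and 89 and 113 in the value table. The number of arrays, the lack of flags and negative controls, and signals near background limit the precision of small changes and of dim genes. Of 90 named genes called between NS-GFP4+ and NS-GFP1+, 70 kept the call wherever they were tested. This covers every alternative that leaves the threshold in place and every left-out array. A gene that a filter removed was not tested there and was not counted as lost. The stricter filter left 11604 of 12556 genes, so the count is least informative for dim genes. Those that lost it under some alternative were Birc5, Bub1, C1qa, C1qc, Ccnf, Cd34, Cdca8, Flt3, H2-DMa, Hoxa5, Ifih1, Ly6g, Mx1, Ndn, Nkg7, Prim1, Rab27b, Rfc5, Sphk1 and Wdr43. For the changed counts below the cause was not tested, except that stricter thresholds call fewer genes by construction.

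Counts are given for NS-GFP4+ against NS-GFP1+ (2037), NS-GFP2+ against NS-GFP1+ (84), NS-GFP3+ against NS-GFP2+ (0), NS-GFP4+ against NS-GFP3+ (291), the linear trend (1990), the difference between the steps (5), any difference (1257) and the lists (15), where they moved by over 1.5 times. With the offset of 50 the difference between the steps gave 15. Without a filter the first step gave 45, the last 127 and the difference 0. The stricter filter gave 8 for the difference, and all probes 49 for the first step. The value table gave 2 for the middle step, the intensity trend 9 for the difference. Array weights, whose fit did not fully converge, gave 4087 for the ends, 652 for the first step, 437 for the last, 3833 for the trend, 24 for the difference and 3083 for any difference.

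By the deposited log2 values, 10 of 12 arrays correlated best with their own replicate number, and by the signals 6 of 11. The replicate block gave 3101 for the ends, 339, 12 and 823 for the steps in order, 2998 for the trend, 27 for the difference and 2253 for any difference. With the value table and the block together, chosen after seeing the data, these were 3278, 368, 28, 775, 3288, 13 and 2262. Of the list calls in the steps, the block added immediate early genes in the first (0.0451) and middle step (0.0127) and megakaryocyte genes in the middle step (0.000691). It ended those of nucleolar (0.0591), interferon (0.399) and Hox genes (0.0805) in the middle step and of immediate early (0.113) and T and NK cell genes (0.402) in the last. Beyond these and the calls given in the report, it changed no call of a list or named gene.

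An adjusted p below 0.01 gave 1167 for the ends, 15 and 38 for the first and last step, 1150 for the trend, 0 for the difference and 635 for any difference. A log2 fold change of at least 1 left 599, 34 and 110 for the ends, first and last step. Chosen after seeing the data, leaving out the replicate 3 arrays gave 128 and 474 for the first and last step and 1 for the difference, and keeping the repeated signals gave 442 for the last step and 9 for the difference. Only the arrays compared gave 18 and 182 for the first and last step. With an estimated correlation 6 lists passed.

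Leaving out 1 array gave 1469 to 2111 for the ends, 19 to 88, 0 to 13 and 41 to 383 for the steps in order, 1469 to 2148 for the trend, 0 to 18 for the difference, 820 to 1388 for any difference and 14 to 16 for the lists. The interferon list passed under several settings (adjusted p = 0.00301 to 0.0448). By fry the MHC class II list did not pass (0.0726), while the cell-cycle inhibitor (0.00201) and stromal lists (0.000855) did.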

Other observations

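The family test and its explanation were chosen after the results were seen.

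Genes of the Tceal and Bex families, small related proteins encoded mostly on the X chromosome and linked to transcription elongation and to growth signalling, included several genes that rose in NS-GFP4+. Tceal3 (3.56), Tceal6 (2.62, adjusted p = 2.78e-05) and Tceal5 (2.06, adjusted p = 4.42e-06) rose, while Tceal1 (0.54, adjusted p = 0.261), Tceal8 (0.32, adjusted p = 0.0591) and Tceal9 (0.23, adjusted p = 0.218) did not pass. Bex4 (2.04), Bex1 (1.94) and Bex2 (1.76) rose, Bex6 fell (-1.27, adjusted p = 0.000213) and Bex3 (0.31, adjusted p = 0.148) did not pass.

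The hypothesis that Tceal genes change together was tested over 390 families sharing a symbol stem. The Tceal family, with 6 measured genes and a mean of 1.55, had an adjusted p of 0.00308 with the preset correlation. With an estimated correlation each of the 390 families had an adjusted p of at least 0.999. That version therefore decides nothing about Tceal. The Bex family, with 5 measured genes, did not pass (adjusted p = 0.168). The family drew attention through the same values that the test used, and its few members keep the hypothesis open. It may be that these genes mark the same cells as the long-term HSC list, which was not tested.

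Probes without a gene name entered only the alternative that tests each probe separately. Of 8184 such probes past the filter, 511 (6.24%) differed between NS-GFP4+ and NS-GFP1+, against 2081 of 17029 named probes (12.2%).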
